A study of Triticum aestivum with 4 samples.

How the data were processed

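Total RNA, 6 µg per sample, was hybridized to Affymetrix wheat arrays, per the labels' protocols. The labels name Cy3 as the label but describe a biotin cRNA protocol, and which holds is not settled here. The parents of P plants were primed at 32 °C by day and 28 °C by night for 2 days at the 7-leaf and the 9-leaf stage, and at 34 °C and 30 °C for 7 days from day 10 after anthesis. The deposited values are linear probe set intensity. MAS5 is the tool named per the submitters' processing notes. The version, the scaling between arrays and detection calls are not given in the sources used here. The columns are near each other in scale but not set to an exact common target: medians were 12.7 (NC), 12.1 (NH), 12.3 (PC) and 12.1 (PH), and means after trimming lay between 66.9 and 69.5.

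Of 61290 probe sets, 175 controls were left out, 111 of them Affymetrix controls and 64 reporter gene probe sets; the plan named only the first kind. Values were kept as deposited. The floor was the 50th percentile of all other values pooled, 12.3. Values below it were raised to it before taking log2, and a fold with a side below the floor is written "at least". A probe set counted when its log2 difference was at least 1 in size. The comparisons were NH against NC, PH against PC, PC against NC and PH against NH, with the overlap of the heat lists, that of the priming lists, and the difference of the heat changes. Overlaps are set beside n1 × n2 / N. With 1 array per group, a single comparison has no test across samples. Across the 4 arrays, an additive limma fit of seed background and temperature, with Benjamini-Hochberg adjusted p-values, was added after the data were seen; it has 1 residual degree of freedom and takes the interaction as error. On simulated arrays of 33561 probe sets, with noise of the same set size for all, it called 200 of 200 changed 4-fold with heat, 10 of 33361 unchanged, and 0 for priming. Neither a priming change nor an interaction was placed, so the run does not show whether the fit would find priming changes. With even noise and no interaction, it gives no rate of false heat calls for the real arrays either.

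Gene names came from the platform annotation of the probe sets. 1273 probe sets had 1 symbol, 0 several, and 59842 none. The 771 symbols were matched to the gene table of the assembly IWGSC CS RefSeq v2.1, used for names only, and 770 matched. For 669 genes the name is a locus symbol alone; 102 have a functional name. Each gene was represented by its brightest probe set by mean log2 intensity, and 612 genes were above the floor on at least 1 array. No coordinates are given, since no genome build is named in the sources used here.

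The comparisons, thresholds, alternatives, gene list patterns and the rule for named genes were fixed before the data were examined. The rule took up to 12 rising and 12 falling genes past 2-fold in both heat or in both priming comparisons, 6 and 6 per single comparison and for the difference of the heat changes, and up to 3 and 3 per gene list. Of the 34 lists, written as patterns on names, 24 matched no gene and the largest matched 4, so none reached the minimum of 5 and none was tested. In their place stand 15 groups of 88 named genes, set later from gene names alone, before the values of these genes were seen. The 7 groups with at least 5 measured genes have a percentile of their median among 10000 random lists of the same size, matched in 20 bins of mean signal; it describes these arrays and is not a p-value. For the other 8 groups, values are given.

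Alternatives were median scaling, quantile normalization, floors at the 25th and 75th percentiles (4.20 and 53.6), a pseudocount equal to the floor in its place, a 3-fold threshold, probe sets without the suffixes for several transcripts, and for groups the mean over all probe sets of a gene. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. The counting step was tested on simulated data built from PC against NC over 61115 probe sets, with changes placed on bright probe sets. It called 46 of 50 changed 2.5-fold, 50 of 50 changed 4-fold, 50 of 50 changed 8-fold and 5 of 50 changed 1.5-fold. Of 60915 probe sets with no change placed, 249 passed 2-fold; the simulated noise was drawn from the differences of this same pair.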

Results

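Gene expression was measured in leaves of bread wheat (*Triticum aestivum*), cultivar Yangmai 16, with 1 Affymetrix wheat array for each of 4 groups. The plants were the progeny of parents that had either been left unprimed (N) or been heat-primed (P), and they were grown either without heat (C) or with heat (H) after anthesis, which gives the groups NC, NH, PC and PH. Heated progeny stood at 34 °C by day and 30 °C by night for 6 days from day 10 after anthesis, and the others at 26 °C and 22 °C. The design asks how heat changes leaf expression, whether priming of the parents leaves a mark on the progeny, and whether the heat response differs between the seed backgrounds. There were no replicates within a group, so no value below has a replicate error, and single comparisons have no p-value. Differences are described by a 2-fold rule, and the number of arrays limits their precision. Of 61115 probe sets, 33561 (54.9%) exceeded the intensity floor of 12.3 on at least 1 array, with 30265 to 30938 above it per array.

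Arrays of the same temperature resembled each other most. Over all probe sets, log2 intensities of NC and PC had a Pearson correlation of 0.993 and those of NH and PH 0.989, against 0.936 for NC and NH and 0.946 for PC and PH. These correlations are across probe sets, which are not independent replicates. The poly-A control RNAs added to the samples were 1.87 times as bright on NH as on NC (median of 36 probe sets) and 0.557 times as bright on PH as on NH. The hybridization controls, 27 probe sets, had median ratios of 1.02 and 0.857 for the same pairs. The ratio of 3' to 5' signal for ubiquitin was 0.645 on NC, 0.929 on NH, 0.750 on PC and 0.992 on PH. For sucrose synthase it was 50.9, 60.2, 45.2 and 55.1, with 5' signal below the floor on NC and PC (5.86 and 6.11). Both ratios were higher with heat in each seed background. A difference in RNA quality between heated and other leaves was not tested.

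In progeny of unprimed plants, some of the named photosynthesis genes were lower with heat by 2-fold or more. FBP, fructose bisphosphatase, fell 15.1-fold from an intensity of 1692 on NC to 112 on NH. PRK, phosphoribulokinase of the Calvin cycle, fell 4.62-fold, petC, the Rieske protein of the cytochrome b6/f complex, 3.36-fold, and Trx-M, thioredoxin m, 5.69-fold. Of the 7 measured genes of the photosynthesis group, 4 passed 2-fold downward and 0 upward, with a median log2 difference of -1.75, lower than in each of 10000 random gene lists matched on signal. PsbO and PsbP, of the oxygen-evolving complex of photosystem II, had log2 differences of -0.67 and -0.98. The gene named rbcl held the highest value of each array, 15575 to 16875 and so stood at the top of the measured scale; 5 of its 11 measured probe sets were lower by 2-fold or more in NH. Among genes of other groups, GAPN, the non-phosphorylating glyceraldehyde-3-phosphate dehydrogenase, fell 46.2-fold, Pgk-1, phosphoglycerate kinase, 11.1-fold, and AGA.1, an ADP-glucose pyrophosphorylase subunit, 8.27-fold.

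The remaining groups differed in how many genes passed 2-fold in the same plants, where 87 rose and 111 fell among the 612 measured genes with a symbol. Tubulins and profilin had a median of -1.05 (percentile 1.47 among matched random lists), with 4 of 7 genes 2-fold lower, among them the beta-tubulin tubb1 (4.39-fold). Of 5 histones and high mobility group proteins, 3 fell, with a median of -1.21 at percentile 5.32, which was -0.78 without the probe set types that can match several transcripts. The histone H2B wcH2B-8 fell 8.55-fold. In the methyl transfer and adenine salvage group, 3 of 5 genes fell and 1 rose, with a median of -1.29 at percentile 2.09. SAHH, S-adenosylhomocysteine hydrolase, fell 2.44-fold, COMT1, caffeic acid O-methyltransferase, 2.46-fold, and PEAMT1, phosphoethanolamine N-methyltransferase, at least 42.8-fold. When the same types were left out, 2 genes of this group remained and its median was 0.68. Of 6 redox and detoxification enzymes, 3 fell and 1 rose (median -0.79, percentile 5.75). The catalase CAT1 fell 2.41-fold and lgul, glyoxalase I, 3.28-fold, while PCS1, phytochelatin synthase, rose at least 4.40-fold. Translation genes had a median of -0.21 at percentile 33.5, with 2 of 7 lower. The xylanase inhibitor XIP-I rose 7.59-fold to 9759, whereas PR5, a thaumatin-like pathogenesis-related protein, fell at least 16.0-fold and the beta-glucosidase TaGlu1a fell 3.56-fold. Of 3 measured defence genes, 1 thus rose and 2 fell. Of 4 starch and fructan genes, 1 fell and 1 rose: 1-FEH, a fructan exohydrolase, rose 3.22-fold. Of 4 transport and cell wall genes, 1 fell, the lipid transfer protein LTP3 (2.89-fold). Both measured genes of the glycolysis group, GAPN and Pgk-1, fell.

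Of 7 stress and desiccation genes with names on this array, 4 were measured, and 0 of these passed 2-fold. The small heat shock protein gene hsp16.9A was below the floor on all 4 arrays, as were COR410 and EM, so their response to heat was not measured. The 4 measured genes had log2 differences from -0.01 to 0.91, the last for FKBP70, a peptidyl-prolyl isomerase. LEA1, Rab15 and EMH2 lay near the floor, at 15.5, 22.4 and 22.6 on NC. For these genes a 2-fold fall could not be seen, only a rise. As markers of grain, 5 of 11 storage protein and purothionin genes were measured, with a median of 0.74 at percentile 98.9. With the floor at the 75th percentile (53.6) that median was 0.00 by construction. Gli-8, LMW-GS and THI1.1 lay below that floor on all 4 arrays, with highest values of 16.5, 24.9 and 22.5. The avenin-like gene avnla rose at least 53.7-fold to 659 on NH; avnlb had 342 on NC and 571 on NH. The serpin Serpin-Z2A rose at least 4.06-fold; WMAI-1, an amylase inhibitor, had -0.09. The anther gene raftin1b lay between 13.4 and 16.8 on all arrays and raftin1a below the floor. Of the gibberellin 20-oxidases, GA20ox1d was the measured gene. It fell by at least 0.36 on the log2 scale, with NH below the floor.

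Across the array, 3615 probe sets were 2-fold or more higher and 3440 lower in NH than in NC, 21.6% of the 32695 above the floor in either. Among genes with a symbol, many of those with wide changes have a locus symbol alone. Examples follow, and probe sets without a symbol are not ranked here. LOC606323 rose from 74.1 to 9166, LOC100037518 from 97.1 to 6848 and LOC542830 from 74.2 to 3696. LOC542947 fell from 6673 to 20.4, LOC780599 from 803 to 19.4 and LOC543436 from 1200 to 23.6.

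In progeny of primed plants, heat lowered 2 of the 7 photosynthesis genes by 2-fold or more. FBP fell 4.93-fold and Trx-M had a log2 difference of -1.58, and the group's median was -0.81 (percentile 0.42). PRK and petC had log2 differences of -0.98 and -0.81. GAPN fell 13.3-fold, Pgk-1 4.92-fold and AGA.1 4.90-fold. Tubulins and profilin had a median of -1.51 (percentile 0.08) and histones and high mobility group proteins -1.10 (percentile 6.04). With the floor at the 75th percentile, these medians were -0.92 and -0.34. Methyl transfer genes had -2.08 (percentile 0.485; 0.33 over the 2 genes left without the probe set types for several transcripts), redox enzymes -0.67 (percentile 6.18) and translation genes -0.19 (percentile 46.6). SAHH fell 4.25-fold and COMT1 4.22-fold. XIP-I rose 6.91-fold and avnla at least 5.94-fold, and PR5 fell at least 11.9-fold. Storage protein genes had a median of 0.40 at percentile 96.5, and 0.00 by construction with the floor at the 75th percentile. Some genes past 2-fold in unprimed progeny did not pass here: LTP3 had -0.62, 1-FEH 0.55, TaGlu1a -0.07, and PIMT, protein isoaspartyl methyltransferase, 0.61. Serpin-Z2A, at 4.09 on PC and 15.1 on PH, had at least 0.30. With PC below the floor, whether it changed 2-fold is not settled. In all, 3145 probe sets were higher and 3241 lower, 19.7% of 32454; among genes with a symbol, 66 rose and 103 fell.

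The changes with heat were largely shared by the seed backgrounds. Of the probe sets 2-fold higher, 2340 were so in both, against 339 for independent lists, and of those lower, 2580 against 332. In opposite directions, 5 moved past 2-fold. An additive limma fit of seed background and temperature over the 4 arrays, added after the data were seen, takes the difference between backgrounds as its error, with 1 residual degree of freedom. At a Benjamini-Hochberg adjusted p under 0.05 it called 5288 of 33561 probe sets higher and 4667 lower with heat, of which 2989 and 3135 also passed 2-fold. The comparisons share no array, and their log2 differences had a Pearson correlation of 0.895 and a Spearman correlation of 0.812 across 33561 probe sets. LOC606323 rose by 6.95 and 7.66 on the log2 scale in the N and P backgrounds, and LOC542947 had -8.35 and -7.56. Other genes past 2-fold in both included LOC543338, LOC606307, LOC543060, LOC606366, LOC543150, LOC543101, XIP-I, LOC543201 and LOC606308 upward. Downward they included LOC543355, LOC542825, LOC542839, LOC543420, GAPN, LOC542871, wcH2B-8, LOC543106 and LOC542847.

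**Figure D1:**
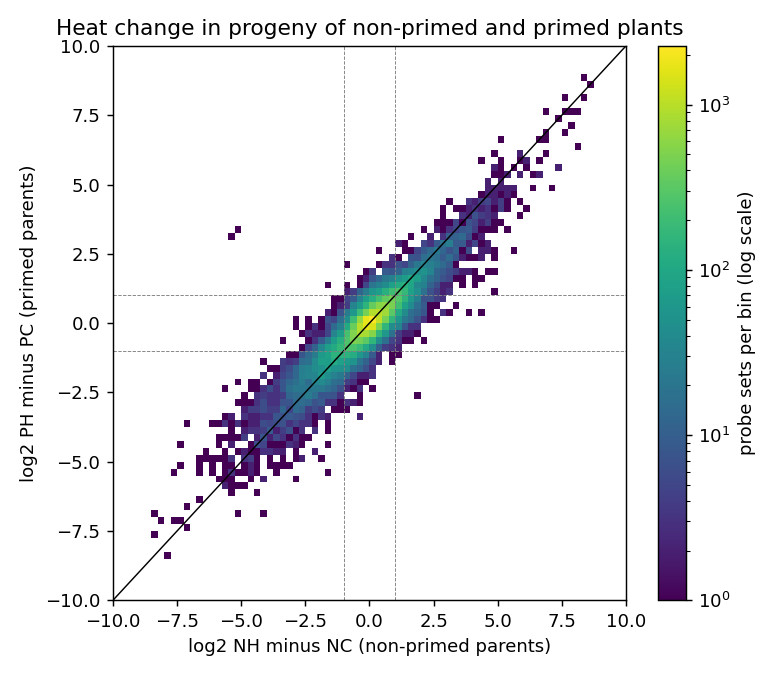
Log2 difference with heat in progeny of unprimed plants (x axis) against progeny of primed plants (y axis), for 33561 probe sets counted in square bins on a log colour scale; dashed lines mark 2-fold and the solid line equal change. Most bins lie along the line, with a Pearson correlation of 0.895 across probe sets.

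Without heat, progeny of primed and unprimed plants differed little. PC and NC differed by 2-fold or more at 109 probe sets upward and 134 downward, 0.761% of 31915, and among genes with a symbol at 5 upward and 11 downward. The photosynthesis group had a median of 0.04 (percentile 52.7), and 0 of its 7 genes passed 2-fold. In the 7 groups with at least 5 measured genes, 0 genes passed 2-fold, and the methyl transfer median of -0.21 had percentile 5.03; over the 2 genes left without the probe set types for several transcripts it was 0.35. Among genes with a symbol and above the floor on both arrays, the largest declines were LOC543201, from 185 to 30.0, LOC543197, from 1404 to 252, and LOC543150, from 199.7 to 50.1. LOC543090 rose from 159 to 391 and LOC606330 from 833 to 1781. TaGlu1a fell 2.51-fold, from 53.8 to 21.4.

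Under heat, 2 of the 7 photosynthesis genes were 2-fold or more higher in progeny of primed plants. FBP was 2.83-fold and PRK 2.74-fold higher in PH than in NH, and petC and Trx-M had log2 differences of 0.98 and 0.96. The 6 genes other than rbcl each had a difference of at least 0.38, and the median over all 7 of 0.96 lay above those of all 10000 matched random lists. GAPN was 3.27-fold and Pgk-1 2.14-fold higher, and LOC543106 stood at 166 against 30.5. In the opposite direction, SAHH was 2.24-fold and COMT1 2.35-fold lower in PH, avnla 9.04-fold lower and Serpin-Z2A 3.30-fold lower. LOC100125738 stood at 132 against 682. The tubulin and profilin median was -0.37 (percentile 1.49) and that of redox enzymes 0.26 (percentile 97.7), each with 0 genes past 2-fold. Storage protein genes had -0.26 (percentile 6.50), methyl transfer genes -0.18 (percentile 20.6), histones 0.08 (percentile 74.5) and translation genes -0.02 (percentile 48.5). Over the array, 715 probe sets were higher and 472 lower, 3.77% of 31462. Among genes with a symbol the balance was the reverse, with 11 higher and 30 lower. At 3-fold the balance over the array also turned, to 100 higher and 133 lower. The poly-A control ratio of 0.557 belongs to this same pair of arrays.

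**Figure D2:**
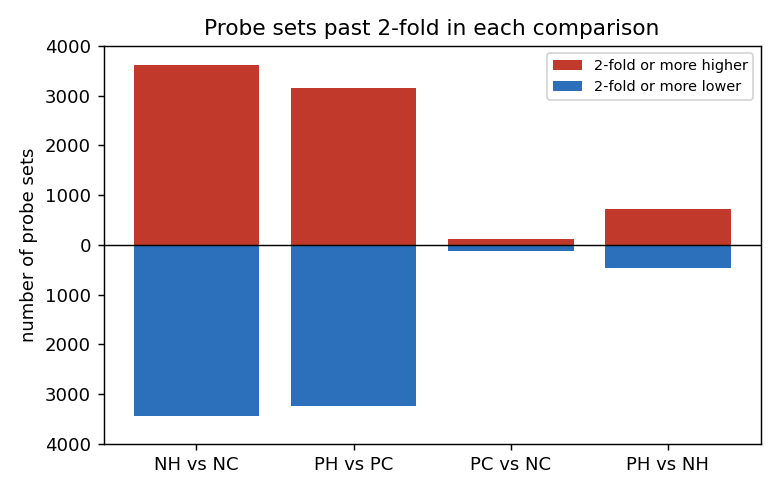
Number of probe sets 2-fold or more higher (above 0) and lower (below 0) in each comparison, from 1 array per group. The heat comparisons have 3615 and 3440, and 3145 and 3241, against 109 and 134 for PC vs NC and 715 and 472 for PH vs NH.

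Few probe sets differed with priming at both temperatures. In both, 27 were 2-fold lower in progeny of primed plants, against 1.88 for independent lists, and 7 higher, against 2.32. In opposite directions, 8 were higher without and lower with heat, against 1.53, and 3 the reverse, against 2.85. The additive limma fit called 0 probe sets for priming after Benjamini-Hochberg adjustment (smallest adjusted p = 0.879), with 1423 of 33561 at an unadjusted p under 0.05. The log2 differences at the 2 temperatures had a Pearson correlation of 0.092 and a Spearman correlation of 0.073. None of the genes with a symbol was higher at both, and 5 were lower. LOC543201 had -2.62 without and -2.15 with heat, LOC543150 -1.99 and -2.18, LOC542799 -1.33 and -1.31, LOC606352 -1.47 and -1.24, and LOC543197 -2.48 and -1.03. All 5 values come from probe set types that can match several transcripts. Without these types, LOC543150 had -0.13 and -0.19 and LOC606352 -1.22 and -0.64, and the other 3 genes had no probe set left. LOC543150 also turned there from a rise to -0.046 for PH against PC.

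The heat change differed between the seed backgrounds by 2-fold or more at 765 probe sets upward and 761 downward, without an error estimate. In the photosynthesis group the difference had a median of 0.92, above all 10000 matched lists. The difference, NH against NC and PH against NH all use the NH array, so their extreme percentiles for this group are not separate results. Elsewhere the difference had medians of -0.49 for methyl transfer (percentile 1.91), -0.38 for tubulins and profilin (5.15) and -0.26 for storage proteins (13.9). For redox enzymes it was 0.12 (77.0), for translation -0.05 (57.0) and for histones -0.02 (48.2). Among genes above the floor on all 4 arrays, the highest values were those of LOC543106 (2.38), GAPN (1.79), TaGlu1a (1.76) and FBP (1.62). The lowest were those of LOC543090 (-3.04), LOC100037560 (-2.03), LOC543422, at 347, 290, 465 and 97.4 on NC, NH, PC and PH, and LOC606308 (-1.90). 1-FEH had -1.13, and avnla, below the floor on NC and PC, -3.18. Among 3154 probe sets whose mean rise over both backgrounds passed 2-fold, the median rise was 1.57 in unprimed and 1.40 in primed progeny, and 65.8% rose less in the primed. Among 3259 that fell, the medians were 1.75 and 1.59, and 59.2% fell less. The values for unprimed progeny rest on 1 NH array, on which the poly-A controls were 1.87 times as bright as on NC. How far this array accounts for the difference was not tested.

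**Figure D3:**
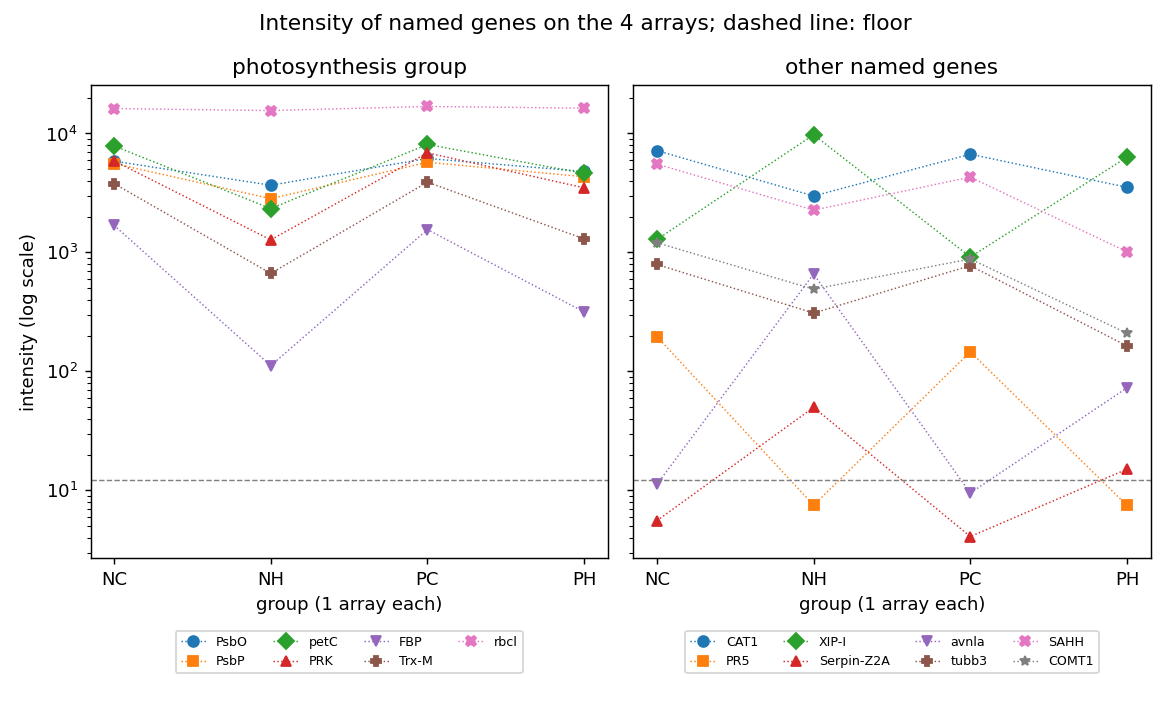
Deposited intensity (log scale) on the 4 arrays of the 7 photosynthesis genes (left) and of 8 other named genes (right), 1 point per array, with the floor of 12.3 dashed. FBP goes from 1692 on NC to 112 on NH and from 1557 on PC to 316 on PH.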

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

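Among the tests in this part, that of the poly-A controls was chosen after its result was seen.

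Control probe sets, which no comparison uses and which cover both added RNAs and wheat genes, carried signal that differed between arrays. The 3' probe set for sucrose synthase, a wheat gene, was 3.90 times as bright on NH as on NC and 3.70 times as bright on PH as on PC. It thus rose with heat in both seed backgrounds, while its ratios with priming were 0.925 for PC over NC and 0.878 for PH over NH. The poly-A controls were 1.87 times as bright on NH as on NC, but 0.812 times as bright on PH as on PC. At 5 probe sets the heat change passed 2-fold in opposite directions in the seed backgrounds; the difference was not tested. Of these, a probe set without a gene symbol, picked after its values were seen, had 449 on NC, 11.0 on NH, 7.92 on PC and 129.9 on PH.

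PH and NH differed at 4.88 times as many probe sets as PC and NC. Noise of dim probe sets was argued against, since with the floor at the 75th percentile the ratio was 5.44. Whether probe sets moved on their own stays open: the test used the 805 called probe sets without the suffixes for several transcripts, of which 160 had another such probe set in the same transcript cluster. In 68.4% of these 316 pairings the other moved the same way, between the bounds set beforehand, against 61.8% over all measured probe sets of this type and 80.6% for PC against NC. A difference in RNA input or quality on the NH array may contribute and cannot be told apart from priming with 1 array per group: the poly-A controls had a PH over NH ratio of 0.557, and were 1.44 times as bright on NH as on PC. An effect of priming under heat is a biological alternative, as is variation between plants, and neither was tested.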

How the results depend on the processing

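With 1 array per group, replicates within a single comparison could not be paired. The additive fit over all 4 arrays, added after the data were seen, takes heat within each seed background and priming within each temperature. It called 0 higher and 0 lower probe sets for priming, and 5288 and 4667 for heat, of which 2989 and 3135 also passed 2-fold. No array could be left out either; comparisons without NH are PH against PC and PC against NC. Counts are given as higher, then lower, in the order NH against NC, PH against PC, PC against NC, PH against NH, difference of the heat change, heat in both backgrounds, priming at both temperatures. Under median scaling and quantile normalization every such count stayed within 1.5 times the reported one. The balance of higher to lower turned in some: under median scaling to 128 and 114 for PC against NC and 3325 and 3146 for PH against PC, under quantile normalization to 3406 and 3582 for NH against NC, and the difference became 676 and 856 under median scaling. With the floor at the 75th percentile they were 2388 and 2176, 1958 and 2071, 47 and 63, 330 and 268, 339 and 399, 1556 and 1672, 3 and 12. At 3-fold they were 1580 and 1916, 1257 and 1651, 7 and 51, 100 and 133, 139 and 166, 1024 and 1319, 1 and 7. There the balance turned for NH against NC, PH against NH and the difference. Without the probe set types for several transcripts, those moved by over 1.5 times were 2366 and 2238 for NH against NC, 2049 lower for PH against PC, 82 lower for PC against NC, 289 lower for PH against NH, 472 lower for the difference, 1621 lower for heat in both, and 4 and 15 for priming at both temperatures. With the pseudocount, PC against NC had 45 and 86, PH against NH 379 and 314, and the difference 419 and 459. With the floor at the 25th percentile, 12 were higher with priming at both temperatures. A stricter floor, threshold or probe set filter admits fewer probe sets by construction. Likewise, a lower floor admits more, and a pseudocount narrows the differences between values above the floor. The cause of the other moves was not tested.

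Group medians were held to a tolerance of 0.3, and all 35 stayed within it under median scaling, quantile normalization, the floor at the 25th percentile and the pseudocount. With the floor at the 75th percentile the storage protein medians were 0.00 for NH against NC and 0.00 for PH against PC. Both were fixed by that floor, since Gli-8, LMW-GS and THI1.1 lay below it on every array. With the same floor, the histone median for PH against PC was -0.34 and the tubulin median -0.92. The tubulin median for PH against PC was -1.12 as the mean of all probe sets. Without the types for several transcripts the histone median for NH against NC was -0.78. There, 2 methyl transfer genes remained, with medians of 0.68 for NH against NC, 0.33 for PH against PC and 0.35 for PC against NC. The photosynthesis median for PH against NH ranged from 0.95 to 0.97. Of 160 gene values past 2-fold, 159 stayed past it under median scaling and 158 under quantile normalization, while 20 were lost with the floor at the 75th percentile and 9 with the pseudocount. Of those with a probe set left under that filter, 108 stayed past it and 14 did not, and LOC543150 turned from a rise to -0.046 for PH against PC through another probe set; the cause was not tested. Signal near the floor limits what can be measured: 27473 probe sets were above it on all arrays.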

Other observations

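Of the 27 probe sets that were lower in progeny of primed plants at both temperatures, 16 were 2-fold higher and 5 lower in NH than in NC, against 10.8% and 10.2% of all measured probe sets. Both arrays of this comparison also served to select the 27. A probe set without a gene symbol, picked after its values were seen, had 55.9 on NC, 1048 on NH, 18.6 on PC and 131.8 on PH. Of the 715 probe sets higher in PH than in NH, 33.6% were 2-fold lower and 22.5% higher in PH than in PC, with a median of 0.26. Of the 472 lower, the shares were 24.8% and 30.3%, with a median of 0.20, and over all measured probe sets 9.66% and 9.37%. This comparison shares PH and so leans to the same sign. In NH against NC, which shares NH and leans to the other sign, 46.7% of the 715 were lower and 1.26% higher, and of the 472, 13.6% and 65.3%.

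The tests of independent lists and of matched random lists below were chosen after their results were seen. The minimum of 10 other probe sets was also set then, as was the use of the interquartile range for the bright probe sets.

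The photosynthesis group had a median of 0.96 for PH against NH, with 2 of 7 genes past 2-fold, and was picked for this from 35 medians. A remaining difference in scale was looked for in array medians and by quantile normalization, which cannot decide it. The array medians were 12.1 on NH and 12.1 on PH, as deposited, near the floor and far below the intensities of these genes. With arrays so alike, quantile normalization could hardly move the group's median, which was 0.97 after it and 0.96 before. Scaling done before deposit is not given and cannot be judged this way. A shift of all bright probe sets was argued against by a median of 0.094 over 732 others as bright on NC, with an interquartile range of 0.69. The percentile of 100 among matched lists cannot exclude a chance choice, since the group was picked for its median. A smaller loss of photosynthesis transcripts under heat in primed progeny may be the biological reading, as a hypothesis only. RNA input on the NH array, the poly-A ratio being 0.557, and variation between plants may also account for it and stay open with 1 array per group.

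The 27 shared declines were 14.3 times the number for independent lists, and the 8 higher without and lower with heat also exceeded their 1.53. The number for independent lists takes every probe set as equally likely to pass 2-fold. The excess therefore cannot tell a shared priming change from probe sets that vary more between any arrays. On direction the values are mixed. Of the 134 probe sets lower without heat, 27 were lower and 3 higher with heat, the latter against 2.85, and 56.0% had the same sign. Of the 109 higher without heat, 7 were higher and 8 lower with heat, and 39.4% had the same sign. The additive fit called 0 probe sets for priming, but whether it could find such changes was not tested. A sequence variant under single probe sets may account for some of them and stays open: the 6 other measured probe sets of the same clusters had a median change of -0.90, from -1.23 to 1.36, and 6 are too few to decide. A difference inherited from the primed parents, and one between seed lots, were not tested.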
